A study of Mus musculus with 2 samples.

How the data were processed

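Chromatin accessibility was measured by DNase-seq in heart tissue of adult female mice of the hybrid strain B6CASTF1/J, aged 18 to 20 months per the labels. In DNase-seq the nuclease DNase I cuts open chromatin, the released ends are sequenced, and regions with many cuts are called as peaks. The 2 libraries form 1 group and are named replicate 1 and replicate 2 as the labels number them. The labels give separate tissue samples under 1 donor record, and whether they came from separate animals is not stated, so every p-value and SD measures only the spread within or between these samples, which may be technical. The series holds 1 group, so no comparison between groups was made.

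The peak lists were made from each library's own alignment in mm10 coordinates, per the labels and the deposited file descriptions. The aligner and the peak caller are not given in the sources used here. The authors deposited 2 lists per library with a signal value for each peak. All signal values below 1 were whole multiples of a single step within 0.02 of a step, as a scaling by the number of reads would give. If the scale were the usual one, the steps would imply 1.79 times as many reads in replicate 2 as in replicate 1. Nothing in the sources used here states this scaling, so the ratio is an inference and the depth itself is unknown. The deposited false discovery rate (FDR) file of each library gives a p-value adjusted as an FDR of the cut rate for each stretch of bases, and no value in it exceeded 0.05. Every peak of the longer lists overlapped a stretch with FDR of 0.05 or less, and every peak of the shorter lists overlapped a stretch with FDR of 0.001 or less. The deposited footprint lists hold short protected stretches inside open chromatin, and the value beside each footprint was the constant 0.01 in both libraries, read here as an FDR threshold, which is not stated.

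The rule fixed before the data were examined took, of the 2 peak lists, the list with the smaller median width and, at equal widths, the list with more peaks. Median widths were 200 bp for both lists of replicate 1, and 202 and 200 bp for the longer and shorter list of replicate 2. These were treated as equal, a choice made once the widths were known, and the longer lists used. For replicate 2 this departs from the rule as written. The literal reading, the longer list of replicate 1 with the shorter list of replicate 2, follows the rule as written. It was run only as an alternative, added after the data were seen.

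Peaks were called shared when they overlapped a peak of the other library by at least 1 bp. The chance level came from 100 random circular shifts along each chromosome. Correlations are across peaks, which are not independent replicates, so they carry no p-value. Annotation was GENCODE M21 on the GRCm38.p6 reference, the same build as mm10, and every interval of the 6 peak and footprint files lay inside its chromosomes. It gave 21829 protein-coding genes with 54322 start sites, after 24 gene records with a repeated symbol were left out. A promoter was 1000 bp to each side of any start site of a protein-coding gene. A territory was the gene with 10 kb to each side.

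A set of 32 gene lists was fixed before the data were examined. The names Ahsp, Tf and Amy2b were not matched in the annotation. List members with a promoter peak in both libraries were compared with all other protein-coding genes by Fisher's exact test. The other genes include the olfactory and vomeronasal receptor families, also among CpG-poor genes, and the tests were not repeated without them. Peaks per territory were compared with 100000 random lists matched on territory length decile by a permutation test, whose smallest two-sided p is 2e-05. Differences between the libraries were tested by permutation of genes on the percentile of promoter peak signal, for 26 lists with at least 5 members, with a smallest p of 1e-05. A set of 39 consensus motifs, read on both strands, was searched in 150 bp around the centre of shared peaks and in windows of the same width 1000 bp away, outside all peaks. In footprints, with 5 bp added to each side, the control was a window of the same width in the same peak outside any footprint. Motifs were tested by Fisher's exact test, and a motif in footprints was called when it passed in the same direction in both libraries. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each family, and the threshold was 0.05. Genes, peaks and windows are not independent replicates, so these tests describe these libraries.

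Each test was checked on simulated data in 20 simulations per test. The promoter test called 85% of changed lists and 1.59% of unchanged lists among 21829 genes. Changed lists were open at 97% or 15%, other genes at 67%. The territory test called 72.5% of lists given 2.5 or 0.3 times the peaks and 0.455% of unchanged lists among 21829 genes. The replicate difference test called 100% of lists shifted by 0.8 on the log2 scale and 1.46% of unchanged lists. It was simulated among 20366 genes, while 14679 genes were compared in the data. The motif test called 100% of motifs placed in 4% of regions and 1.21% of the others in 20000 regions. These rates hold for the simulated sizes and do not give the power for smaller effects. Confidence intervals of shares are 95% Wilson intervals and cover counting error only.

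Named genes follow a rule fixed before the data were examined: for each list, up to 4 members with the highest mean promoter peak signal among those with a peak in both libraries, and up to 2 members, first in alphabetical order, with a peak in neither. The rule also takes the 5 densest territories of at least 30 kb, the 5 strongest shared distal peaks on autosomes and X, and for each library the 3 genes with the strongest promoter peak that the other library lacks. A list of 26 noncoding genes was written after other results but before its own values were seen, and 24 of these names were matched (not Mir143hg and Norad). Some single genes and 1 motif that these rules name are not reported here.

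Alternatives covered the peak list, the upper part of each list by signal, the overlap that counts as shared (50% of both peaks, or centres within 75 bp), the promoter window (250 and 2500 bp), the start site, the territory (no flank, or 50 kb), the background genes (those with a promoter CpG observed over expected ratio under 0.6 within 500 bp), control windows matched in GC content in bins of 5 percentage points, reversed consensus sequences, the signal scale, and each library alone. All computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Alignments and reads were not used here, so allele-specific signal of the hybrid was not analysed here.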

Results

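The data are maps of open chromatin in the heart of aged female mice, made by DNase-seq in 2 replicate libraries. Replicate 1 held 128123 peaks covering 27.98 Mb and replicate 2 held 202168 peaks covering 47.94 Mb, a mean of 165146 ± 52358 peaks (SD, n = 2). The median peak signal was 0.665 in replicate 1 and 0.428 in replicate 2, in the authors' units. Footprints numbered 387107 in replicate 1 and 657867 in replicate 2. The labels describe 1 tissue without a treatment or a contrast. The comparisons are therefore between the replicate libraries, and within them between gene groups, peak classes and sequence motifs.

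The first question is which open regions both libraries share. Among the list members with a promoter peak in both, the highest mean signals were those of Myl4 (a myosin light chain of the atria, in a peak shared with Cdc27), Rplp0 (a ribosomal protein), Eif4a1 (translation initiation), Esrra (a nuclear receptor of energy metabolism) and Jun (an AP-1 subunit). Their promoter peak signals were 15.8 ± 4.02, 15.3 ± 1.82, 15.2 ± 2.70, 15.1 ± 3.73 and 14.9 ± 4.91 (SD, n = 2). Of the peaks of replicate 1, 88.2% (95% Wilson interval 88.1 to 88.4) overlapped a peak of replicate 2, against 3.48% for shifted peaks. With the literal reading of the peak list rule the share was 75.7%. Of the peaks of replicate 2, 55.5% (55.3 to 55.7) overlapped a peak of replicate 1, against 2.23% for shifted peaks. Both libraries covered 22.8 Mb of the 53.2 Mb that either covered, or 42.8%.

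Sharing followed peak height. In the lowest signal decile 57.5% of replicate 1 peaks and 8.44% of replicate 2 peaks were shared. In the highest decile 99.2% and 99.3% were shared. The 89966 peaks of replicate 2 without a partner had a median signal of 0.263, against 0.744 for its shared peaks. Across the 113044 shared peaks of replicate 1, log2 signal in the 2 libraries had a Spearman correlation of 0.931 and a Pearson correlation of 0.948, across peaks that are not independent replicates. The SD of the log2 ratio between the libraries was 0.44 over these peaks, so a single peak differing by less than this is within their spread.

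**Figure D1:**
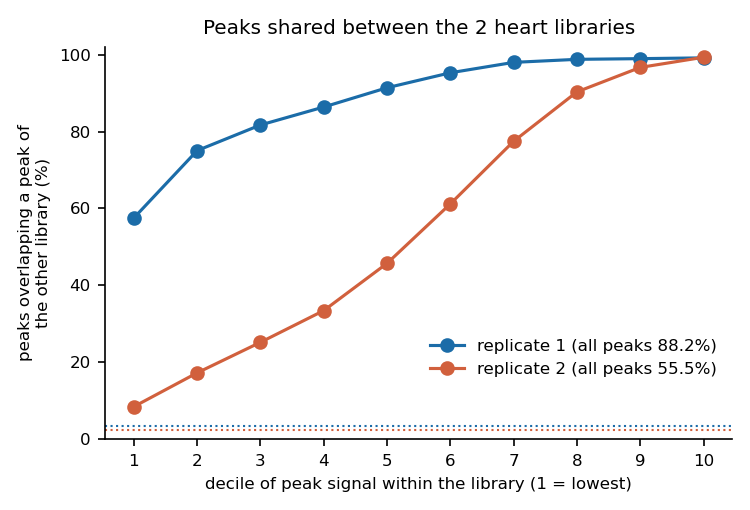
Share of peaks (%, vertical axis) of each heart library that overlap a peak of the other library by at least 1 bp, by decile of peak signal within the library (horizontal axis), with dotted lines for randomly shifted peaks. Sharing reaches 99.2% in replicate 1 and 99.3% in replicate 2 in the highest decile and falls to 57.5% and 8.44% in the lowest.

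Promoters of protein-coding genes held 22.3% of the peaks of replicate 1 and 17.1% of replicate 2, with a mean of 19.7% ± 3.71 (SD, n = 2), and make up 2.44% of the genome. The promoter share was thus 8.09 times the genomic share. Introns held 38.4% ± 2.25 of peaks against 35.1% of the genome, exons outside promoters 4.13% ± 0.0742 against 2.33%, and intergenic sequence 37.8% ± 1.39 against 60.1%. Promoter peaks were also the highest class, with a median signal of 1.57 in replicate 1 and 0.943 in replicate 2. Intergenic peaks had medians of 0.556 and 0.357. Of the 21829 protein-coding genes, 14679 (67.2%) had a promoter peak in both libraries and 6265 (28.7%) in neither.

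Genes of the cardiomyocyte were accessible at their promoters more often than other genes, though mostly with low peaks. The other genes include 1133 olfactory and 330 vomeronasal receptor genes, of which 18 and 2 had a promoter peak in both libraries. These closed families lower the share of other genes (67.2%), so the excess over the remaining genes is smaller. No test left them out. For members with a promoter peak in both libraries, the median signal percentile was 23.5 for sarcomere and 24.7 for ion channel genes. It was 38.2 for cardiac transcription factors and 86.0 for ubiquitous genes. Of 30 sarcomere and Z-disc genes, the contractile apparatus, 26 had a promoter peak in both libraries (86.7%, odds ratio 3.17, Fisher's exact test, adjusted p = 0.0438). They included Tpm1 (tropomyosin, 10.3 ± 4.76), Myl4, Myom1 (myomesin, 9.32 ± 4.77) and Cryab (a chaperone of the Z-disc, 3.26 ± 0.158), as promoter peak signal with SD over the 2 libraries. The Tpm1 peak lay in an intron at chromosome 9:67043881-67044120 (GRCm38) in replicate 1. The peaks of Myl4, Myom1 and Cryab also lay in promoters of Cdc27, Myl12a and Hspb2 respectively. Myl7, the atrial regulatory light chain, and Myom3 had a promoter peak in neither library. Of 28 ion channel and calcium handling genes, 25 were accessible (89.3%, adjusted p = 0.0212 by Fisher's exact test), among them Camk2d (calcium/calmodulin-dependent kinase, 10.3 ± 3.31), Asph (7.05 ± 0.928) and Kcnj2 (inward rectifier potassium channel, 5.92 ± 1.35), while Sln, the sarcolipin of the atria, had no peak. The peak of Tmem38a (10.9 ± 2.38) also lay in the promoter of Smim7. The sarcomere call ended when only the most upstream start site of each gene counted (83.3% open, adjusted p = 0.0570, Fisher's exact test), with the shorter peak lists (80.0%, 0.0710) and with the upper 50% of peaks by signal (76.7%, 0.105), and the ion channel call ended with the most upstream start site (82.1%, 0.0716) and with the 250 bp promoter (82.1%, 0.0656).

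Cardiac transcription factors were accessible in 24 of 25 cases (96.0%, odds ratio 11.7, Fisher's exact test, adjusted p = 0.00222). Besides Esrra, the highest were Hey2 (a Notch target, 9.43 ± 1.90), Mef2a (7.97 ± 0.943) and Tead1 (7.05 ± 0.293). Hand1 had no promoter peak in either library. With the most upstream start site alone the call ended for cardiac transcription factors (84.0%, adjusted p = 0.0578 by Fisher's exact test) and for glycolysis genes (85.0%, 0.0852). Genes of cardiac energy supply were open almost throughout. All 24 fatty acid oxidation genes had a promoter peak in both libraries (adjusted p = 0.000533 by Fisher's exact test), led by Acsl1 (9.84 ± 1.62), Acadm (9.79 ± 2.66) and Acaa2 (7.39 ± 1.04). All 20 genes of glycolysis and glucose uptake were accessible (adjusted p = 0.00142 by Fisher's exact test), led by Pdk1 (10.5 ± 2.98), Hk1 (8.53 ± 0.361) and Gapdh (8.48 ± 2.73). Of 28 respiratory chain subunits 27 were accessible (adjusted p = 0.00131 by Fisher's exact test), led by Cycs (cytochrome c, 10.8 ± 3.97), Sdhc and Uqcrfs1 (8.84 ± 0.442), with Atp5o the exception.

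Among natriuretic peptide and hormone genes 6 of 8 had a promoter peak in both libraries (75%, adjusted p = 1 by Fisher's exact test). The highest were Pam (a peptide-amidating enzyme, 3.401 ± 1.08), Npr1 (1.87 ± 0.107) and Npr3 (1.85 ± 0.177), which encode natriuretic peptide receptors. Nppb (brain natriuretic peptide) had a promoter peak of 1.11 ± 0.204 upstream of its start, at chromosome 4:147985341-147985500 in replicate 1. Its neighbour Nppa (atrial natriuretic peptide) had a promoter peak in neither library. Between 10 kb upstream of Nppb and 10 kb past Nppa, replicate 1 had 3 peaks and replicate 2 had 5, and the strongest at the far end lay in Clcn6 at chromosome 4:148008481-148008680 in both.

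**Figure D2:**
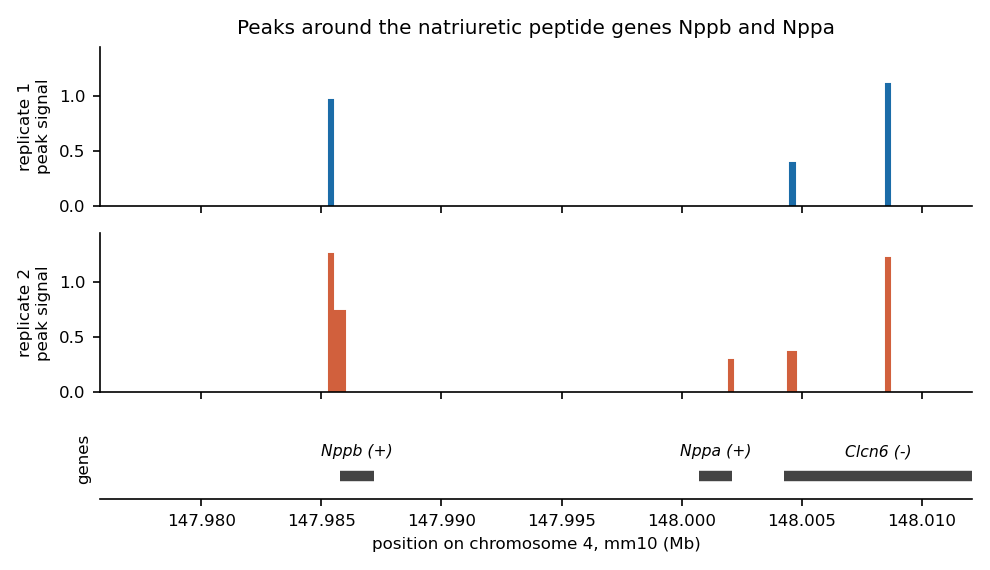
Peaks of each heart library (bars, height in the authors' signal units, width to scale) and genes (bars below, strand in brackets) around Nppb and Nppa on chromosome 4, with position in Mb on the horizontal axis. Both libraries have a peak just upstream of Nppb (0.967 in replicate 1 and 1.26 in replicate 2) and none at the start of Nppa.

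Of the other cell types that a heart holds, endothelial and fibroblast genes were accessible most often. The median signal percentile of their members with a peak was low, 25.5 and 28.2 respectively. Of 28 endothelial genes 27 had a promoter peak in both libraries (96.4%, adjusted p = 0.00131 by Fisher's exact test), led by Ets1 (8.33 ± 2.22), Rgcc (5.33 ± 2.48), Sox7 (3.37 ± 0.573) and Eng (a TGF-beta co-receptor, 2.98 ± 0.696). Of 24 fibroblast and matrix genes 22 did (91.7%, Fisher's exact test, adjusted p = 0.0133), led by Col1a1 (6.72 ± 0.0340), Vim (4.77 ± 0.922), Pdgfra (3.38 ± 0.652) and Fn1 (3.20 ± 0.593), though this call ended with the upper 50% of peaks by signal (75%, adjusted p = 0.231 by Fisher's exact test). Smooth muscle and pericyte genes did not pass the test with 14 of 16 (Fisher's exact test, adjusted p = 0.146, and 0.0421 in replicate 1 alone), with Smtn at 5.48 ± 0.829 and Myh11 at 1.75 ± 0.269. Epicardial genes had 7 of 12, with Tbx18 at 2.54 ± 0.0738, macrophage genes 12 of 20, with Cd14 at 1.19 ± 0.130 and Spi1 at 1.149 ± 0.529, adipocyte genes 10 of 16, with Lipe at 8.17 ± 0.745, and Schwann cell and neuron genes 11 of 16, with Pmp22 at 3.71 ± 0.176, and none of these lists passed the test. Macrophage genes were called below other genes with the shorter peak lists (35%, adjusted p = 0.0245 by Fisher's exact test) and with the upper 50% of peaks by signal (25%, 0.00326). The literal reading of the peak list rule, which is the rule as written but was run after the data were seen, also called them below (40%, adjusted p = 0.0432 by Fisher's exact test). Among CpG-poor genes macrophage genes lay the other way without passing (60% against 36.5% of other genes there, adjusted p = 0.0932, Fisher's exact test). Epicardial genes were called below with the shorter lists (33.3%, adjusted p = 0.0489 by Fisher's exact test). Blood cell genes were accessible less often than other genes. Lymphoid genes had 5 of 18 (27.8%, adjusted p = 0.00173 by Fisher's exact test) and erythroid genes 3 of 11 (27.3%, adjusted p = 0.0132). The highest lymphoid value, Foxp3 at 4.20 ± 1.38, came from a peak shared with the promoter of Ppp1r3f, and Cd3e had no peak. Tfrc, the transferrin receptor, which many cell types use, was the highest of the erythroid list at 5.60 ± 1.85.

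Genes of other tissues were accessible less often in 7 of 10 lists and more often in none. Fisher's exact test gave 4 of 19 hepatocyte genes (adjusted p = 0.000382), 5 of 16 keratinocyte genes (0.00923), 3 of 15 pancreas genes (0.00108), 4 of 16 intestine and kidney genes (0.00173), 1 of 18 germ cell genes (7.53e-07), 18 of 1133 olfactory receptor genes and 2 of 330 vomeronasal receptor genes (2.41e-156). Alb, the liver's serum albumin, and Apoa1 had no promoter peak. The highest hepatocyte values belonged to Apoh (5.83 ± 2.40) and Foxa3 (4.93 ± 1.03), whose peaks also lay in promoters of Prkca and Sympk. Dazl (3.51 ± 0.567) was the germ cell gene with a peak, and Olfr433 (2.90 ± 0.308) was the highest olfactory receptor. The vomeronasal gene Vmn1r4 (7.40 ± 2.97) shared its peak with Nt5c3. Brain neuron genes (13 of 20, with Rbfox3 at 2.38 ± 0.102), embryonic genes (8 of 16, with Esrrb at 1.81 ± 0.307) and skeletal muscle genes (9 of 20, Fisher's exact test, adjusted p = 0.0737) did not pass. However, 3 alternatives called embryonic and skeletal muscle genes below other genes by Fisher's exact test: the 250 bp promoter (25% and 30%, adjusted p = 0.00444 and 0.0062), the shorter peak lists (25% and 30%, 0.00517 and 0.00692) and the upper 50% of peaks by signal (31.25% and 35%, 0.0310 and 0.0322). The highest skeletal muscle values, Actn3 (7.21 ± 1.32) and Mylpf (4.02 ± 0.887), came from peaks shared with Zdhhc24 and Tbc1d10b, and Myh1 had no peak.

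Genes of general cell functions were accessible in every member for 5 of 6 lists. These were 25 of 25 ubiquitous genes, 16 of 16 circadian clock genes, 20 of 20 immediate early and stress genes, 15 of 15 senescence and p53 response genes and 16 of 16 cell cycle genes, with adjusted p of 0.000387, 0.00481, 0.00142, 0.00776 and 0.00481 by Fisher's exact test. Clock promoters were among the strongest, with Nr1d1 at 12.02 ± 3.21, Per1 at 11.03 ± 3.05 (from different peaks in the libraries) and Per2 at 10.7 ± 3.796. So were those of the immediate early genes Jund (12.02 ± 4.30), Atf3 (11.1 ± 1.45) and Klf2 (9.44 ± 2.14). Trp53inp1 (10.6 ± 2.83) led the p53 list, in which Mdm2 was at 8.11 ± 0.933, and Ccne1 (11.01 ± 0.945) and Mcm5 (10.5 ± 2.05) led the cell cycle list. Homeobox cluster genes had 11 of 18 accessible promoters, with Hoxa10 at 1.91 ± 0.476.

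In all, 13 of 32 lists were above and 9 below other genes. Within the 10605 genes with CpG-poor promoters 10 of 31 lists passed, 7 above and 3 below: sarcomere (19 of 23 against 36.4% of other genes there, adjusted p = 4.79e-05 by Fisher's exact test), ion channel (10 of 13, 0.0196), fatty acid oxidation and glycolysis (8 of 8 each, 0.00139), endothelial (16 of 17, 1.13e-05), fibroblast (16 of 18, 4.79e-05) and also smooth muscle genes (10 of 12, 0.00480), with germ cell (0 of 12, 0.0190), olfactory and vomeronasal genes below. There the calls of cardiac transcription factors (4 of 5, adjusted p = 0.122 by Fisher's exact test), respiratory chain (3 of 4, 0.224) and lymphoid (1 of 14, 0.0678), erythroid, hepatocyte, keratinocyte, pancreas, intestine and kidney, ubiquitous, clock, p53 and cell cycle genes ended, and the immediate early list had no member.

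**Figure D3:**
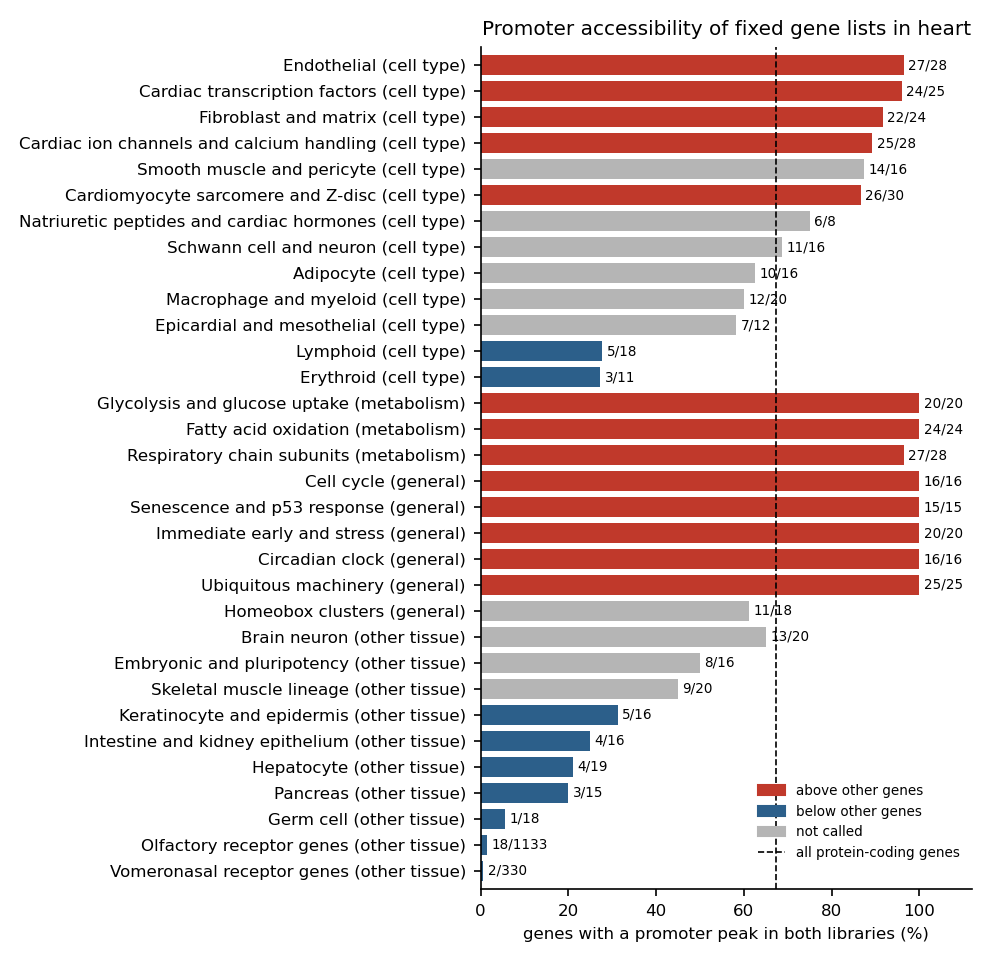
Share of genes with a promoter peak in both heart libraries (%, horizontal axis) for 32 gene lists, with the counts beside each bar and the value of all protein-coding genes (67.2%) as a dashed line. Red lists lie above and blue lists below other genes by Fisher's exact test with Benjamini-Hochberg adjustment: metabolic, endothelial and fibroblast lists, 5 of 6 general lists and the cardiac lists except natriuretic peptides lie above, and most lists of other tissues below.

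The number of shared peaks around a gene showed which gene groups are surrounded by open elements. Immediate early and stress genes had 9.85 shared peaks per territory, 3.31 times the mean of random lists of matched territory length (2.97 ± 0.710, SD over random lists), and circadian clock genes 11.7 peaks, 2.57 times. Both reached the smallest p the permutation test can give (2e-05, adjusted p = 0.00016). Cardiac transcription factors had 16.0 peaks, 2.22 times the random mean (permutation test, adjusted p = 0.0296), fatty acid oxidation genes 7.63 peaks, 1.70 times (0.00448), glycolysis genes 7.60 peaks, 1.75 times (0.0296), and ubiquitous genes 6.08 peaks, 1.78 times (0.00448). Fewer peaks lay around intestine and kidney genes (0.487 times, adjusted p = 0.0238), germ cell genes (0.463 times, 0.0216), olfactory receptor genes (0.0527 times, 0.00016) and vomeronasal receptor genes (0.0324 times, 0.00016), by permutation test. Ion channel genes (1.54 times, permutation test, adjusted p = 0.0649), fibroblast genes (1.505 times, 0.0649), endothelial genes (1.46 times, 0.0794) and sarcomere genes (1.30 times, 0.192) did not pass, nor did homeobox cluster genes (1.39 times, 0.226), which turned below random lists with the shorter peak lists (0.908 times) and with the literal reading of the peak list rule (0.933 times). In replicate 2 alone sarcomere genes (2.27 times, permutation test, adjusted p = 0.0167), ion channel genes (1.74 times, 0.0460) and homeobox cluster genes (2.15 times, 0.00256) passed, and in replicate 1 alone homeobox cluster (1.83 times, 0.0306) and respiratory chain genes (1.596 times, 0.0385). Other alternatives ended calls. With promoter peaks left out the calls of glycolysis (permutation test, adjusted p = 0.107), ubiquitous (0.0969), intestine and kidney (0.107) and germ cell genes (0.141) ended, and with the gene body alone those of glycolysis (0.0583), ubiquitous (0.197) and intestine and kidney genes (0.0891). The shorter peak lists ended those of fatty acid oxidation and germ cell genes (0.0739 each), the upper 50% of peaks by signal that of germ cell genes (0.0656), and flanks of 50 kb those of intestine and kidney (0.215) and germ cell genes (0.648). The same alternatives added calls above random lists for sarcomere, endothelial and smooth muscle genes with 50 kb flanks, for endothelial and respiratory chain genes with the upper 50% of peaks and for senescence and p53 response genes with the shorter lists, and calls below for erythroid, hepatocyte, keratinocyte and pancreas genes in at least 1 of them. When random lists were also matched on having a promoter peak, an alternative chosen after the data were seen, clock (2.06 times) and immediate early genes (2.06 times) stayed above and the receptor families below (0.130 and 0.0811 times), with adjusted p of 0.00016 each, while the call of cardiac transcription factors (1.92 times, permutation test, adjusted p = 0.0771) and the other 5 calls ended. The densest territories were those of Midn (chromosome 10:80138272-80168368, 26 shared peaks, 86.4 per 100 kb), Epha1 (83.4), Nfatc4 (77.9), Adamtsl4 (75.7) and Bcl9l (75.4), against a median of 7.32 per 100 kb over 14077 territories.

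The strongest distal peaks lay in a ribosomal RNA gene, in gene bodies and in intergenic sequence. The highest, at chromosome 17:39846781-39846920, had a signal of 78.0 ± 5.12 (SD, n = 2) and lay in an exon of the ribosomal RNA gene CT010467.1. The next lay in an exon of Lars2 (mitochondrial leucyl-tRNA synthetase) at chromosome 9:123461881-123462140 (42.9 ± 3.78), in an intron of Kpna1 and an exon of the antisense gene Gm15564 at chromosome 16:35981661-35981840 (40.7 ± 10.1), in intergenic sequence at chromosome 3:5860361-5860530 (39.4 ± 4.05), and in an intron of Il31ra at chromosome 13:112578141-112578340 (35.7 ± 7.40). These coordinates are of the peaks of replicate 1. Between 56.0% and 100% of the 31-base words of the last 4 peaks also occur elsewhere in the reference. The nearest protein-coding start sites were of Esp38 (103.7 kb away), Limd1 (16.7 kb), Kpna1 (1.56 kb), Gm8797 (109.6 kb) and Il31ra (2.42 kb).

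In distal open regions the motif of CTCF had the highest odds ratio. CTCF, which anchors chromatin loops, was found in 5.93% of 87020 shared distal peaks and 0.0471% of flanking windows (odds ratio 133.8). The motifs of REST (a repressor of neuronal genes, odds ratio 70.4, adjusted p = 5.05e-65 by Fisher's exact test), NFI (32.3, 1.34e-34), C/EBP (9.24, 2.85e-40), SP/KLF (6.48, 2.32e-101) and CRE (4.79, 5.91e-55) followed, then the CAGCTG E-box (3.16), AP-1 (5.68% against 2.56%, odds ratio 2.30), the ROR/REV-ERB clock element (1.72) and TEAD (1.56). GATA passed narrowly (1.09, adjusted p = 0.0311 by Fisher's exact test). Of 39 motifs 24 were above and 9 below their flanks.

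The AT-rich motifs depended on base composition, since distal peaks held 52.4% GC and their flanks 44.9%. MEF2, a regulator of muscle genes, was below the flanks (1.95% against 2.59%, odds ratio 0.750, adjusted p = 8.73e-23 by Fisher's exact test) but 3.10 times above windows matched in GC content (2.23% against 0.731%, 2.9e-126). IRF and POU turned in the same way (odds ratios 1.48 and 1.21 in matched windows), and FOX (1.73) and RUNX (1.36) passed in matched windows only. NKX2 (1.17, adjusted p = 0.103) and SRF (1.12, 0.0971) were below the flanks and did not pass in matched windows by Fisher's exact test. With matched windows 28 motifs were above and 3 below, and SP/KLF fell from 6.48 to 2.17. The matching kept 71296 of the 87020 distal peaks. Both controls called 23 motifs above, among them CTCF, REST, NFI, C/EBP, AP-1, TEAD and GATA, and 3 below, TBX, ERR and CRX/OTX, of which ERR turned above its flanks in replicate 2 alone (1.07). Of the 23, 6 were also above when the consensus was read reversed, among them SP/KLF (5.39), CAGCTG (2.12) and CRE (1.63). The reversed SP/KLF consensus keeps most of the forward sequence, so for SP/KLF it is no independent control.

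**Figure D4:**
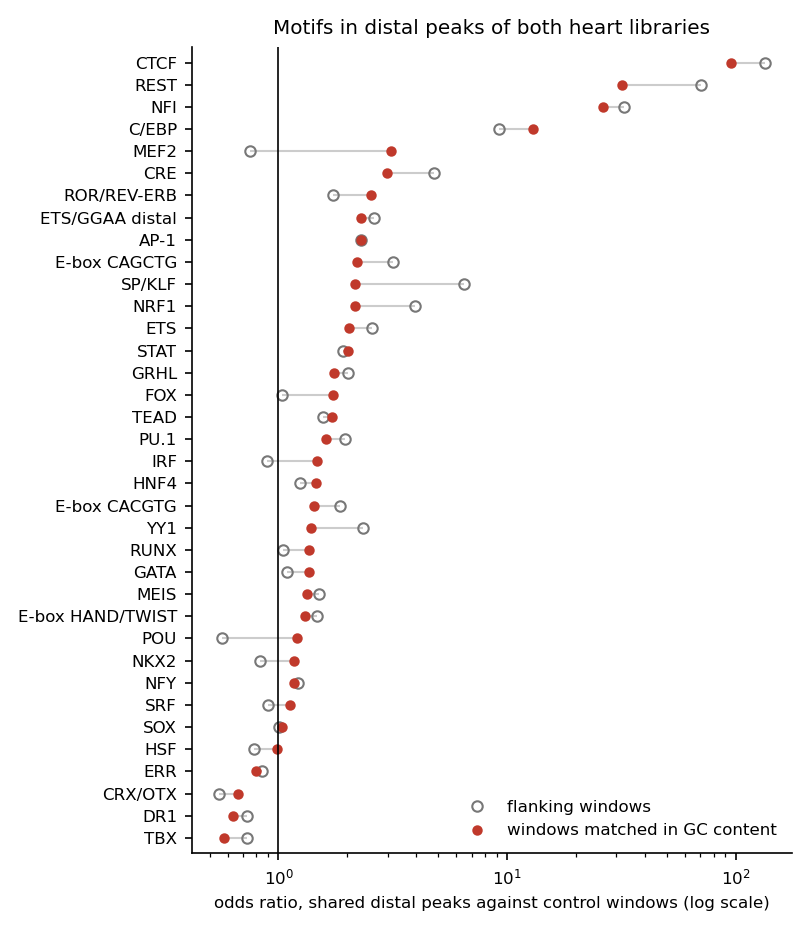
Odds ratio (log scale, horizontal axis) of each motif in shared distal peaks against flanking windows (open points) and against windows matched in GC content (red points), for motifs present in every set, without 1 motif that is left out. CTCF has the highest ratio with both controls, and MEF2 moves from 0.750 to 3.10.

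In 26024 shared promoter peaks the motifs of NRF1 (odds ratio 75.1, adjusted p = 1.13e-75 by Fisher's exact test), YY1 (64.7, 1.33e-64), SP/KLF (34.6), CTCF (28.2, 8.58e-82), CRE (17.1, 1.34e-118), ETS (12.4, 1.36e-54), C/EBP (8.41, 2.04e-11) and the NFY CCAAT box (6.04, 6.08e-298) were above the flanks. The reversed SP/KLF consensus was also above (23.8, adjusted p = 7.29e-216 by Fisher's exact test). REST occurred in 43 promoter peaks and in 0 of 34278 flanking windows. Promoter peaks held 62.7% GC against 45.6% in their flanks, and 15 motifs were above and 15 below. With windows matched in GC content 18 were above and 3 below: MEF2 turned from 0.226 to 1.74, FOX from 0.507 to 1.71 and POU from 0.617 to 1.66, while NRF1 (23.6), CTCF (29.8), YY1 (12.7), CRE (11.1) and NFY (5.78) stayed above. SP/KLF also stayed above but fell from 34.6 to 3.38. The matching kept 10384 of the 26024 promoter peaks, with a mean GC of 54.8%, so it describes a GC-poorer part of them.

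Footprints had a median width of 10 bp in replicate 1 and 9 bp in replicate 2, and 82.5% and 83.6% lay in peaks of their library (mean 83.0% ± 0.781, SD, n = 2). Of the footprints of replicate 1, 60.0% overlapped a footprint of replicate 2 (95% Wilson interval 59.9 to 60.2), against 0.621% for shifted footprints. Of those of replicate 2, 35.7% (35.6 to 35.8) did so, against 0.371%. Footprints of 20 bp or wider were shared in 97.4% and 86.1% of cases. Against windows of the same peaks outside footprints, NRF1 had odds ratios of 268.2 in replicate 1 and 84.6 in replicate 2, CTCF 67.7 and 162.1, NFI 77.02 and 32.8, SP/KLF 34.9 and 35.6, C/EBP 20.1 and 11.4, CRE 18.1 and 14.8, and the CACGTG E-box 2.64 and 2.21. REST was in 124 footprints of replicate 1 and 197 of replicate 2 and in 0 control windows. GATA, which was above its flanks in distal peaks, was below its control in footprints of both libraries (0.657 and 0.706, adjusted p = 3.16e-06 and 2.18e-08 by Fisher's exact test), and TEAD (1.001 and 0.974) and ROR/REV-ERB (0.654 and 1.102) were not called. FOX was also below in both (0.251 and 0.271, adjusted p = 2.0e-60 and 6.94e-90 by Fisher's exact test). In all 14 motifs were above and 7 below in both libraries, and 16 and 3 with windows matched in GC content, an alternative chosen after the data were seen. There GATA, MEIS, POU, PU.1 and YY1 were no longer called, and TEAD (1.24 and 1.148), IRF (1.63 and 1.22) and HNF4 (1.65 and 1.51) were called above. MEF2 lay below its control in replicate 1 (0.698) and above in replicate 2 (1.18), so it was not called.

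Between the libraries no gene list passed the test of promoter signal rank. The test was simulated only for shifts of 0.8 on the log2 scale, so smaller shifts could be missed. The largest shift was in skeletal muscle genes, 7.03 percentile points higher in replicate 2 (SD 8.80 over 9 genes, higher in 7 of 9, permutation test, p = 0.00538, adjusted p = 0.14). Adipocyte genes (5.06 points, higher in 9 of 10) and respiratory chain genes (2.96 points, higher in 20 of 27) also had an unadjusted permutation p under the threshold, making 3 of 26 lists. Sarcomere genes shifted by 2.15 points (SD 6.30, permutation test, adjusted p = 0.398) and cardiac transcription factors by 2.58 points (adjusted p = 0.346). On the log2 scale centred on the library median, where all genes shifted by 0.05, 9 lists were higher in replicate 2 and 1 lower by permutation test: skeletal muscle (0.55, adjusted p = 0.00026), sarcomere (0.32, 0.000433), olfactory receptor (0.38, 0.000433), fibroblast (0.32, 0.00104), smooth muscle (0.37, 0.00187), natriuretic (0.45, 0.0143), adipocyte (0.35, 0.0143), embryonic (0.34, 0.0394), ion channel (0.21, 0.0394) and, lower, epicardial genes (-0.26, 0.0394). These compare 1 library with 1 and carry no replicate check.

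Promoters with a peak in 1 library alone were few, 190 genes in replicate 1 and 695 in replicate 2. The strongest in replicate 1 were Sgk2 (a serine/threonine kinase, signal 1.32), Slc26a10 (1.04) and Slc12a3 (the thiazide-sensitive sodium chloride cotransporter, 0.985). In replicate 2 they were Gm11444 (1.85), Best1 (a chloride channel, 1.42) and Sim1 (a transcription factor, 0.889). The Sgk2 value lay at the 20.2 percentile of promoter signals of its library and that of Gm11444 at the 32.5 percentile.

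The labels call both samples female, and few peaks lay on the Y chromosome, 43 in replicate 1 and 100 in replicate 2. These compare with 2996 and 5377 peaks on the X chromosome.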

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

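The test of Y-linked promoters, and the limit of the word test to words on other chromosomes, were chosen only after the result was seen. The labels call both samples female, and signal on the Y chromosome drew attention because no gene list test singled it out. Its 183 protein-coding genes are among the 21829 genes of those tests. It held 43 peaks in replicate 1, with a highest signal of 3.78, and 100 in replicate 2, with a highest signal of 10.9. Male cells or a mislabelled sample would open the promoters of Ddx3y, Uty, Kdm5d and Eif2s3y, genes that male cells use widely, and 0 of these 4 had a peak in either library, while their X-linked partners Ddx3x (7.80 in replicate 1 and 6.13 in replicate 2), Kdm6a (14.6 and 12.1), Kdm5c (9.93 and 6.30) and Eif2s3x (5.62 and 5.32) had one in both. Reads from sequence that the Y chromosome shares with other chromosomes may be the source: on average 58.7% of the 31-base words of the Y peaks also occur on another chromosome, above the highest of 1000 sets of autosomal peaks (3.68%). Y sequence outside peaks was not scored. The comparison therefore cannot show that the Y peaks hold more shared words than the rest of the Y chromosome. Shared words cover the Y peaks unevenly. Between 90717601 and 90744820 lay 20 peaks of replicate 1 and 28 of replicate 2, with a mean of 21.3% against 78.3% for the other Y peaks. That cluster held the highest Y signal of each library, with medians of 0.605 in replicate 1 and 0.557 in replicate 2. The other Y peaks were low, with medians of 0.0665 and 0.0168, against 0.665 and 0.428 for all peaks of each library. Shared sequence is thus a candidate mainly for low peaks, and the source of the stronger cluster stays open. No biological explanation was tested, since the design holds 1 group.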

How the results depend on the processing

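The literal reading of the peak list rule, the GC-matched windows of footprints, the random lists matched on a promoter peak, and all alternatives for the Y chromosome were chosen after the data were seen. The literal reading is the rule as written before. The equal treatment of widths in the main analysis was chosen once the widths were known. Of 75 alternative values of the main results 48 stayed within their limit and 27 moved. The limit was 1.5 times for a count, and the SD between replicates for the promoter share and footprints inside peaks. For sharing of peaks and footprints it was the Wilson interval, and for the correlation an interval over peaks. These intervals do not measure replicate spread, so small shifts there counted as moved, such as a correlation of 0.933 against 0.931. Of 1316 values for single lists and motifs 1033 kept direction and side of the threshold, 92 lost and 67 gained a call, and 124 turned, 74 of them without a call in either setting. Another 58 values have no finite odds ratio, since a count was 0. Among these, with the consensus reversed, 5 calls were lost (distal REST, and CTCF, YY1, NFI and REST in footprints) and REST at promoters turned (0 of 26024 peaks against 1 of 34278 flanking windows). Distal HNF1 turned in GC-matched windows without a call, and no other alternative ended the REST calls. No paired analysis was possible because the series holds 1 group, so nothing was compared between groups. The upper part of footprints by score was not run, since the score is constant. Leaving out a library gives no value for sharing of peaks or footprints, correlation or replicate differences. Low peaks of 1 library are often missing from the other. Except where the alternative's construction shows the cause, the cause was not tested.

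With the shorter lists the mean number of peaks was 103734, sharing of replicate 1 peaks 91.5%, promoter share 25.9%, footprints inside peaks 64.4% and Y peaks 34.5. With the upper 50% of peaks by signal these were 82746.5 peaks, 97.2% shared, a correlation of 0.910 and 28.9% at promoters. With the literal reading sharing was 75.7%, the correlation 0.933, footprints inside peaks 73.0% and Y peaks 40.5. Sharing was 66.8% at 50% of both peaks (correlation 0.939), 71.5% for centres within 75 bp and 77.2% with equal numbers of top peaks. Promoters of 250 and 2500 bp held 10.9% and 27.2% of peaks. Genes with CpG-poor promoters gave 10 called lists, territories without promoter peaks 6 and lists matched on a promoter peak 4. Whole footprints inside peaks were 80.2%, footprints shared at 50% of both 41.7%, and in shared peaks 63.7%. The log2 scale gave 10 replicate differences. Leaving out a library gave 128123 to 202168 peaks, 17.1% to 22.3% at promoters, 22 to 23 called lists at promoters, 12 to 13 around genes, 387107 to 657867 footprints, 82.5% to 83.6% of them inside peaks, 31 to 32 called motifs in distal peaks, 31 in promoter peaks, 25 to 30 in footprints, and 43 to 100 Y peaks.

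Directions turned as follows. In shares of open promoters against other genes, the 250 bp promoter gave natriuretic genes 50% and Schwann cell and neuron genes 56.25%, the 2500 bp promoter brain neuron genes 80%, the upper 50% of peaks Schwann cell and neuron genes 37.5%, and the shorter lists these and natriuretic genes 62.5% each, as the literal reading did for the former. Among CpG-poor genes macrophage (60%), adipocyte (53.8%), brain neuron (62.5%), skeletal muscle (41.2%) and homeobox genes (50%) lay above other genes. With a peak in either library epicardial, macrophage, brain neuron and skeletal muscle genes (75% each) and homeobox genes (77.8%) lay above and Schwann cell and neuron genes (68.75%) below. Each library alone gave 68.75% for the last in both, brain neuron genes 65% to 75% and homeobox genes 61.1% to 77.8%.

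In peaks around genes against random lists, 50 kb flanks gave Schwann cell and neuron 1.01, brain neuron 0.999 and skeletal muscle 1.17, and the gene body alone macrophage 0.901, Schwann cell and neuron 1.03, embryonic 0.989 and cell cycle 0.735. The literal reading gave homeobox 0.933, the shorter lists natriuretic 0.996 and homeobox 0.908, the upper 50% of peaks brain neuron 0.735 and embryonic 0.776, and promoter peaks left out skeletal muscle 1.02 and cell cycle 0.7504. Lists matched on a promoter peak gave natriuretic 0.974, lymphoid 1.11, hepatocyte 1.05, skeletal muscle 1.102, germ cell 1.08 and cell cycle 0.742. Each library alone gave skeletal muscle 0.910 to 1.147 and cell cycle 0.9397 to 1.01. Replicate differences turned against the shift of all genes for glycolysis (0.0271), endothelial (0.0741) and immediate early genes (0.00654) on the log2 scale, and at 50% of both peaks for glycolysis (-0.0315) and immediate early genes (-0.107 percentile points).

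For motifs these are odds ratios. In GC-matched windows of distal peaks MEF2 was 3.10, SRF 1.12, NKX2 1.17, IRF 1.48 and POU 1.21. At promoters MEF2 was 1.74, GATA 1.09, TEAD 1.14, SRF 1.03, RUNX 1.09, FOX 1.71, IRF 2.12, POU 1.66, SOX 1.01, HNF4 1.501, MEIS 1.09 and ROR/REV-ERB 1.07. In footprints MEF2 was 1.25, TEAD 1.20, SRF 1.41, RUNX 1.151, IRF 1.43, POU 1.04 and ROR/REV-ERB 1.24. With the consensus reversed, distal CTCF was 0.561, NRF1 0, NFY 0.807, YY1 0, GATA 0.672, TEAD 0.779, TBX 1.19, HAND/TWIST 0.367, DR1 1.31, RUNX 0.631, FOX 0.661, HNF4 0.561 and ROR/REV-ERB 0.619. Reversed at promoters, ETS was 0.726, NFY 0.830, AP-1 0.507, STAT 0.524, the distal ETS motif 0.553 and PU.1 0.686. Reversed in footprints, NFY was 0.539, CRE 0.696, AP-1 0.738, HAND/TWIST 0.521, CACGTG 0.853, DR1 0.799999, C/EBP 0.882, STAT 0.598, HNF4 0.654, HSF 0.330, the distal ETS motif 0.444 and GRHL 1.64. A reversed consensus is another sequence of the same base composition, though for SP/KLF it keeps most of the forward sequence. It need not keep CpG sites: the CRE and CACGTG motifs lose theirs. For such motifs it is no control for CpG content. Reversed sequences also turned for motifs that were not called or were below, so a turn alone does not show that a motif is read. The upper 50% of peaks gave distal DR1 of 1.19 and RUNX of 0.981 and promoter AP-1 of 0.951, and the literal reading distal SOX of 0.994 and HNF1 of 1.67. With 10 bp added to footprints MEF2 was 1.199, TEAD 1.03 and ERR 1.04, and in footprints of distal peaks IRF was 1.04. Each library alone gave distal ERR of 0.878 to 1.07 and SOX of 0.992 to 1.08, promoter AP-1 of 0.977 to 1.04, and in footprints MEF2 of 0.698 to 1.18, SRF of 0.750 to 1.26, TEAD of 0.974 to 1.001, ERR of 0.971 to 1.47, IRF of 0.856 to 1.05, STAT of 0.975 to 1.05, ROR/REV-ERB of 0.654 to 1.102, HSF of 0.788 to 1.71 and the distal ETS motif of 0.939 to 1.101.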

Other observations

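Chosen only after the results were seen were the tests of depth by signal and of the ratio after adjustment for signal, and the need for that ratio and for every list to agree in the test of makeup, and the ribosomal RNA test was narrowed to the region of chromosome 17. Noncoding genes, which the gene lists leave out, were open at their annotated start sites in 17 of 24 cases in both libraries. The highest were the nuclear RNA Malat1 (signal 11.5 ± 3.05, SD, n = 2), the small nucleolar RNA hosts Gas5 (9.02 ± 1.75) and Snhg1 (8.16 ± 0.514), and Neat1 (8.02 ± 0.511), the scaffold of paraspeckles. Of the X inactivation centre, Ftx (6.602 ± 1.09), Jpx (2.28 ± 0.301) and Xist (1.95 ± 0.902, from different peaks in the libraries) had peaks in both. Of imprinted RNAs, Kcnq1ot1 (5.31 ± 1.40) and Airn (2.502 ± 0.156) were higher than Meg3 (0.699 ± 0.0457) and H19 (0.352 ± 0.0407). Mhrt, an antisense RNA of the cardiac myosin genes, had a peak of 1.57 ± 0.0232. Mir133a-2, a muscle microRNA, had one of 0.632 ± 0.0216, while Mir1a-1 had a peak in replicate 2 alone (0.401), and Mir208a, Mir499, Mir126a, Mir122, Miat and Hotair had none. The annotation of a microRNA spans only a short stretch, as for Mir208a at chromosome 14:54949060-54949142. The start site of a longer transcript that holds the microRNA was therefore not examined.

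Chromosome X was sparse in shared peaks, with 15.9 per Mb against an autosomal median of 47.4 (35.2 to 69.3, the highest on chromosome 11). It also held fewer per protein-coding gene, 2.74 against a median of 5.58 (3.47 to 7.31). No test was made of these values.

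The 89966 peaks of replicate 2 without a partner in replicate 1 lay in sarcomere territories more often than shared peaks did, 428 against 212 (odds ratio 2.53, Fisher's exact test, adjusted p = 6.24e-29), with Ttn (titin, 52 peaks) and Tnnt2 (cardiac troponin T, 50) holding the most. Ion channel (1.30) and cardiac transcription factor territories (1.25) were also above, and fibroblast (0.738) and adipocyte territories (0.576) below. Depth cannot be told apart from other sources: 9.78% of these peaks overlapped a position of replicate 1 with FDR of 0.05 or less, against 2.81% of shifted peaks and 36.9% in the opposite direction. The bound written before, under 20%, was wrong, because the FDR file holds no value above 0.05, so a site that misses the limit for want of reads looks like a closed one. By signal 48.5% lay below the 10th percentile of replicate 1, against 6.88% of shared peaks. Another makeup of cell types also cannot be told apart: of the 5 lists that differed, 3 (sarcomere, ion channel and cardiac transcription factor) went in the direction of their promoter signal rank and 2 against it (fibroblast, 3.05 percentile points, and adipocyte, 5.06), and none of these rank differences passed. At shared peaks sarcomere genes lay 0.17 above all genes in log2 ratio (26 of 30 genes, permutation test, adjusted p = 0.00576), which fell short after adjustment for signal (0.11, adjusted p = 0.0509). In the same test ion channel genes lay above before (0.22, permutation test, adjusted p = 0.0013) and after adjustment (0.16, 0.00819), and cardiac transcription factor (0.16, 0.0114), fibroblast (0.17, 0.00933) and Schwann cell and neuron genes (0.17, 0.0337) only before. Macrophage genes lay below before (-0.21, 0.00576) and after (-0.27, 0.00078), as did epicardial genes (-0.21, 0.027 and -0.26, 0.00819), and endothelial genes only after (-0.12, 0.0488). If either library could miss such peaks, the peaks of replicate 1 alone would also be above in sarcomere territories, and they were not (odds ratio 0.735, Fisher's exact test, p = 0.223). This met the bound against that explanation written before, an odds ratio of 1 or less. The choice to leave it open was made after the result was seen, because the test does not separate 0.735 from 1. Fibroblast genes went opposite ways in count and ratio (0.738 and 0.17), and no promoter list passed by rank. On the log2 scale of promoter signal, sarcomere (0.32), ion channel (0.21), fibroblast (0.32) and adipocyte genes (0.35) passed as higher in replicate 2. Cardiac transcription factors (0.18) did not pass. Fibroblast and adipocyte genes went against their peak counts there too, so the promoter signal does not settle the makeup on either scale.

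The 4 strongest distal peaks besides the one in the ribosomal RNA gene of chromosome 17 lay in Lars2, Kpna1, Il31ra and intergenic sequence of chromosome 3. Copies of the ribosomal RNA region of chromosome 17, of which 5815 bp were searched, and copies of mitochondrial sequence would share 20-base words with these references, and 0 of 4 peaks did so for either. These 5815 bp may not hold the whole ribosomal RNA unit, so copies of ribosomal RNA sequence outside them were not tested. Sequence present more than once in the reference is a candidate explanation, since 3 of 4 peaks (59.6%, 100% and 58.2% of their 31-base words found elsewhere) lay above the 99th percentile of 996 other distal peaks (56.99%) and the peak in Kpna1 just under it (56.0%). The highest of the other peaks had 85.2%. The measure does not count copies, and no relation between copies and signal was tested. No biological explanation was tested, since the design holds 1 group.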
